A study of Plasmodium falciparum with 2 samples.

How the data were processed

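RNA of untreated and of HDTAB-treated P. falciparum K1 was analysed, each on 1 array, which may hold 1 culture or a pool, with P. falciparum, mosquito and control probe sets. Per the labels' protocols, RNA was extracted with Trizol, purified on a column, treated with DNase, spiked with poly-A RNA, converted to cDNA by a 1-cycle kit that starts from the 3' end of transcripts, and transcribed into biotin-labelled cRNA. Labelling from the 3' end makes 5' probe sets dimmer, and the cRNA is strand-specific. Per the submitters' processing notes the signals came from Affymetrix Expression Console. The version, the background correction, the normalization and the summary method are not given in the sources used here.

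The deposited table held 1 log2 signal per probe set and array, and the authors' values were used as deposited. The log base is not stated. Values reached 14.17, which is above the natural log (11.09) and the log10 (4.82) of the largest value of a 16-bit scanner and below its log2, 16, so log2 was taken from the values. The sorted values of the 2 columns differed by at most 0.20 and shared a maximum, so the 2 distributions are nearly but not exactly the same, and which normalization was used cannot be read from the values. Array signals have no read depth: their precision is limited by the number of arrays. A normalization that aligns the 2 distributions over their whole range could hide a change common to all parasite transcripts. Aligning the middle alone would not, since the median of all probe sets, 2.31 on each array, lies below the background level defined below. Here the sorted values lay within 0.20 of each other over the whole range, above background too, so such a hidden change is not excluded.

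Values are HDTAB minus untreated on the log2 scale, computed with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3. The background of each array was the 95th percentile of its mosquito probe sets. P. falciparum probe sets that shared an ID up to the suffix (CDS or UTR, and x, s or a for probes that match several transcripts) were averaged as 1 target, since no table paired probe sets with genes; 191 of 4293 targets had several probe sets. Targets above background on at least 1 array were counted at 2-fold, using their measured values on both arrays. For targets above background on 1 array only, bounds were taken against the higher of the background level and the target's own dim value. Organisms were read from the ID prefixes, and 290 probe sets with number-only IDs and 937 named by sequence accessions have no organism here. The 346 of these with RC in the ID target the reverse complement of their sequence.

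The samples, the comparison, the alternatives, 26 gene lists and the rule for named genes were fixed before the data were examined. The rule named the 12 targets with the largest rise and the 12 with the largest fall among described genes above background on both arrays, the 3 largest of each direction above background on 1 array, all genes of the phosphatidylcholine and phosphatidylethanolamine pathway, and up to 3 members and the textbook markers of each other list. With no gene names or descriptions it was reduced to the 2 highest and 2 lowest IDs, and all 26 lists (88 members given by ID, the others by description) had 0 members with a probe set ID. Control probe sets with a transcript in their ID were named as well, a choice made after the IDs were seen.

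Groups of probe sets were set against 10000 random lists of P. falciparum probe sets of the same size, matched on mean level in 20 bins. The percentile describes these 2 arrays and is not a p-value. Counting was tested on simulated data for the HDTAB comparison, made from the untreated array with the noise of the mosquito probe sets, over 3629 targets. Changes were planted only in targets with a probe set more than 2 log2 units above the untreated background. Recovery in dimmer targets was not tested. At planted log2 changes of 1.5 and 2.0, 50 of 50 targets each were counted as 2-fold in the right direction, at 1.0 it was 26 of 50, at 0.7 it was 0 of 50, and 0 of 3429 unchanged targets were counted. The last count was fixed by the noise used, since no mosquito probe set differed by more than 0.829. The simulation covers the technical noise of dim probe sets only and leaves out variation between cultures. A shift of 0.2 planted in a list of 100 targets gave a percentile of 100, against 17.6 with no shift. This list test used the same noise, with an SD of 0.18 against 0.43 for the measured targets. Such a shift may therefore be harder to see in measured lists.

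Alternatives were median centring on P. falciparum probe sets, quantile normalization, loess over level (statsmodels 0.14.6, span 0.3), no background filter, the 99th percentile, background passed on both arrays, only probe sets without x, s or a suffix, the brightest probe set of a target, and thresholds of 1.5-fold and 4-fold. Scaling to the hybridisation or poly-A controls, raising dim values to the background level, and counting single probe sets were added after seeing the data.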

Results

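Total RNA from cultures of Plasmodium falciparum K1, a laboratory strain of the human malaria parasite grown in red blood cells, was measured on single-colour Affymetrix arrays. One array held RNA of untreated parasites and 1 held RNA of parasites exposed to hexadecyltrimethylammonium bromide (HDTAB) at 2 µM, which the labels give as its half-inhibitory concentration. HDTAB is a quaternary ammonium compound that the series title names as an inhibitor of choline kinase, the enzyme that phosphorylates choline in the first step of phosphatidylcholine synthesis. Incubation lasted 72 h, and the parasites were trophozoites, the growing blood stage, by their labels. The design text speaks of different cultures being divided into an untreated and a treated part, while 1 array per condition was analysed here, so each array may hold RNA of 1 culture or a pool. There were therefore no replicates, and every difference below describes these 2 arrays, with no test, standard error or p-value between conditions.

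The question was which parasite transcripts differ in level after exposure to the choline kinase inhibitor. Each array gave a log2 signal for 22761 probe sets, of which 4502 carried P. falciparum IDs and 16884 carried mosquito IDs. The mosquito probe sets had no intended target in these cultures, and the 95th percentile of their signals, 2.87 on the untreated array and 2.86 on the HDTAB array, was taken as background. P. falciparum probe sets were above background in 83.3% of cases on the untreated array and in 84.0% on the HDTAB array. Across P. falciparum probe sets the 2 arrays correlated with a Pearson r of 0.989, a value over probe sets within 1 pair of arrays, which are not independent replicates.

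In the signals as deposited, whose distributions are nearly the same on both arrays, most parasite transcripts had similar levels on the 2 arrays. The 4502 probe sets fell on 4293 targets, a target being all probe sets that share an ID up to its suffix, and 3705 targets were above background on at least 1 array. Of these, 52 targets were at least 2-fold higher on the HDTAB array, 69 were at least 2-fold lower, and 3584 (96.7%) lay within 2-fold. At 4-fold, 3 targets were higher and 4 were lower. Among targets above background on both arrays, Pf.3.169.0 differed most. It had a log2 signal of 11.01 untreated and 8.30 after HDTAB, a log2 difference of -2.71 or a level 6.53-fold lower. Pf.7.207.0 went from 9.56 to 7.37, a log2 difference of -2.19 or 4.55-fold lower. The targets with the largest positive difference were Pf.11.257.0, at 3.83 untreated and 6.03 treated (log2 difference 2.20, 4.59-fold), and Pf.6.59.0, at 4.05 and 6.07 (log2 difference 2.02, 4.06-fold). Both were under 4-fold when the arrays were scaled to the hybridisation or poly-A controls, and Pf.6.59.0 with quantile normalization too. Each of these 4 targets was measured by 1 probe set, so no spread over probe sets can be given. The suffixes of both higher ones (s) and of Pf.3.169.0 (a) mark probes that match several transcripts.

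**Figure D1:**
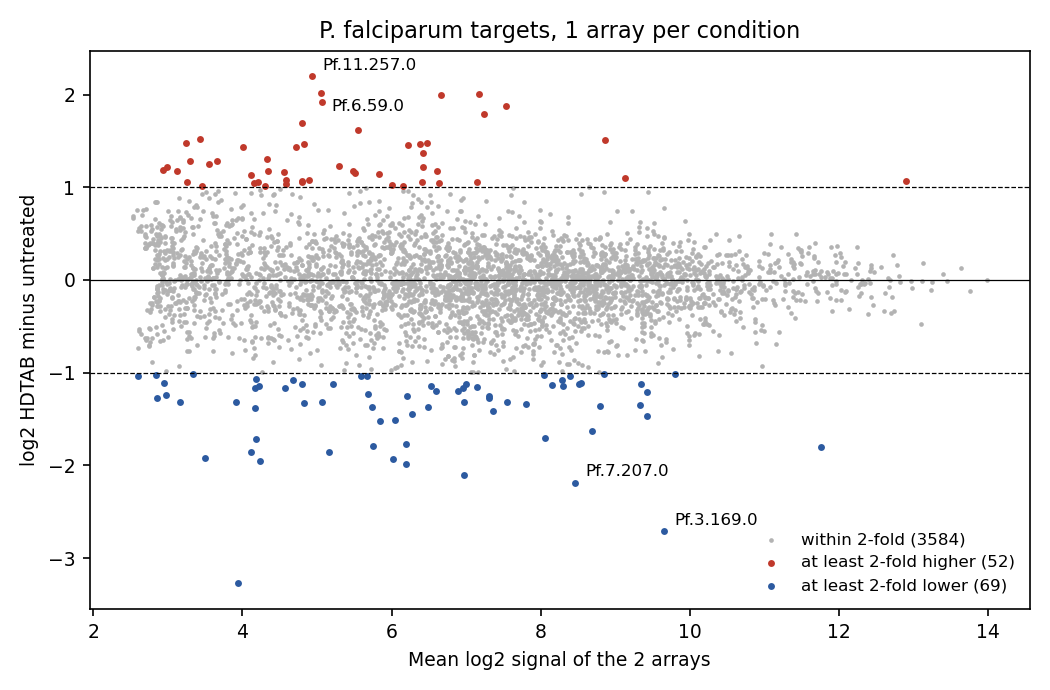
Log2 difference (HDTAB minus untreated, vertical axis) against the mean log2 signal of the 2 arrays (horizontal axis) for 3705 P. falciparum targets above background on at least 1 array, each point being 1 target. Dashed lines mark 2-fold, with 52 targets above the upper line and 69 below the lower one, and the 4 named targets are marked.

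The spread of the mosquito probe sets, used as a measure of technical noise, was smaller than these differences. None of the 16884 mosquito probe sets differed by 2-fold, the largest absolute log2 difference among them being 0.829, and their SD was 0.18. Most of them lay below background, where the narrow range of signals leaves little room for a 2-fold difference. For the 1064 above background on at least 1 array the SD was 0.25, against 0.43 for P. falciparum probe sets filtered the same way. Mosquito probe sets are dim, so the comparison holds for dim signals: between log2 levels of 4 and 5 the SD was 0.21 over 38 mosquito probe sets and 0.55 over 350 P. falciparum probe sets. For 151 measured targets with several probe sets, the pooled SD between probe sets of 1 target was 0.23, and all probe sets of a target moved the same way in 74.8% of them. With few probe sets per target, a common direction often arises by chance alone. Only 3 of the targets counted as 2-fold had several probe sets. Every set moved the same way in 3 of these and was 2-fold in 2. The other counted targets rest on 1 probe set each, with no such check. Other probe sets differed more. The 3 probe sets of parasite actin ran from -0.35 to 1.40 (SD 0.91). Of the 18 probe sets for hybridisation controls, described below, 2 were at least 2-fold higher on the HDTAB array. All 18 of these controls were higher, so the class shifted as a whole, and the 2 do not measure the noise of single probe sets. They show that a 2-fold difference can arise without a change in a parasite transcript. For actin a change in the transcript itself is not excluded. These spreads leave out the variation between cultures, which 1 array per condition cannot give.

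Some targets were above background on 1 array only. The HDTAB array alone measured 97, and 3 of these were at least 2-fold higher by a bound against the background level, the largest with a log2 difference of at least 1.32. The untreated array alone measured 64, of which 2 were at least 2-fold lower after HDTAB by the same bound, the largest being at least 6.57-fold lower. Of the 52 higher and 69 lower targets counted above, 45 and 60 were above background on both arrays. The others were counted through a value below background on 1 array, and only 3 and 2 of them were 2-fold by the bound.

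Probe sets whose IDs name the transcript covered GAPDH, actin and the histidine-rich proteins of the parasite. GAPDH, an enzyme of glycolysis, was 1.48-fold higher on the HDTAB array in the mean of its 4 control probe sets (log2 difference 0.56 ± 0.02, SD over probe sets), a direction that turned to -0.30 when the arrays were scaled to the hybridisation controls and shrank to 0.05 with scaling to the poly-A controls. Actin, a protein of the cytoskeleton, did not move as 1 transcript. Its 5' probe set was 2.64-fold higher (6.96 untreated and 8.36 treated, log2 difference 1.40), its middle probe set differed by 0.10 on the log2 scale, and its 3' probe set was lower (12.84 and 12.49, log2 difference -0.35). The 5' value shrank to 0.54 under scaling to the hybridisation controls and to 0.88 under scaling to the poly-A controls, both under 2-fold, and the 3' value went to -1.22 and -0.87. Neither changed its sign under the scalings tried, while the middle probe set lies below 0 after scaling to either set of added controls. Histidine-rich protein III was at a log2 signal of 6.39 untreated and 6.62 treated in the mean of its 2 probe sets, a log2 difference of 0.24 ± 0.12 (SD over probe sets), which became -0.63 under scaling to the hybridisation controls and -0.28 under scaling to the poly-A controls. Both probe sets of histidine-rich protein II stayed below background on both arrays, with mean log2 signals of 1.96 and 2.17, so no fold is given for it.

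The transcripts of choline kinase itself and of the rest of the phosphatidylcholine and phosphatidylethanolamine pathway could not be picked out, because the IDs of the probe sets are not paired with genes in the sources used here. None of the 22761 IDs was counted as a match to the 5615 genes of the reference table, the 290 number-only IDs being left out of the match by rule. The same holds for the 26 gene lists chosen in advance, which covered lipid synthesis, ring, trophozoite, schizont and gametocyte stages, haemoglobin digestion, glycolysis, heat shock, redox defence, translation, protein turnover and the variant surface antigen families. GAPDH, a member of the glycolysis list, was the only list member with probe sets named in this way. Whether the stages present differed between the conditions is therefore not analysed here.

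Controls added during processing were brighter on the HDTAB array. The labels state that poly-A RNA was added to the RNA before cDNA synthesis. The 24 probe sets for the 4 bacterial transcripts of this kind (Dap, Lys, Phe and Thr) were all higher, with a median log2 difference of 0.52 and a range of 0.32 to 0.91. The 18 probe sets for the hybridisation controls (BioB, BioC, BioD and Cre), which are usually added with the labelled RNA, were all higher too, with a median of 0.86 and a range of 0.44 to 1.03. BioB differed by 0.94 ± 0.10 (SD over 6 probe sets) and Cre, the brightest, by 0.58 ± 0.12 (SD over 4 probe sets). P. falciparum targets had a median log2 difference of -0.02 over the same arrays. Relative to the hybridisation controls that median was -0.88, with 6 targets at least 2-fold higher and 1330 lower, and relative to the poly-A controls it was -0.53, with 9 higher and 435 lower. The counts of 52 and 69 therefore hold for the signals as deposited and depend on how the arrays are scaled.

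Human control probe sets differed in direction. The 6 probe sets of human actin and GAPDH had a mean log2 signal of 4.52 untreated and 4.47 treated, with a median log2 difference of -0.07 and a range from -0.62 to 0.47. The human Alu probe set, for a repeat element of the human genome, was bright on both arrays, at 10.25 untreated and 10.94 treated, a log2 difference of 0.69. Of the 3 HUMRGE probe sets, 1 was above background on both arrays, with a log2 difference of 0.62, 1 was above background on the HDTAB array only and 1 on neither, so no difference is given for the other two.

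**Figure D2:**
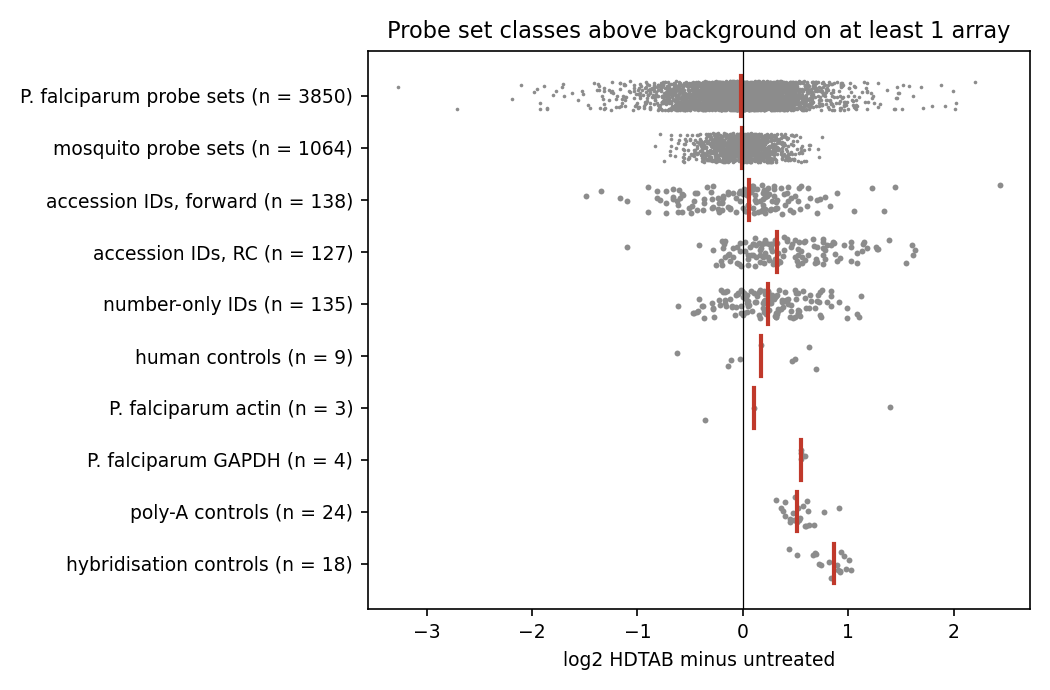
Log2 difference (HDTAB minus untreated, horizontal axis) of single probe sets above background on at least 1 array, by class of ID (vertical axis), with grey points for probe sets and red bars for class medians. The medians are -0.02 for P. falciparum, 0.52 for poly-A controls and 0.86 for hybridisation controls, and RC marks the reverse-complement strand.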

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

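All tests in this part were chosen after the results were seen. With 1 array per condition, none of the values below has a spread between cultures.

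Some classes of probe sets outside the parasite comparison were brighter on the HDTAB array than on the untreated one, while the 1064 mosquito probe sets above background had a median log2 difference of -0.01. The median log2 difference was 0.24 over the 135 probe sets with number-only IDs above background, 101 of which were higher. The human Alu control probe set differed by 0.69. The 127 reverse-complement probe sets above background had a median of 0.32, and 104 of them were higher, while the 138 forward probe sets named by accessions had a median of 0.06.

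The reverse-complement signal was clearest where both strands of a sequence were measured. In 38 such sequences the reverse-complement strand had a median log2 difference of 0.61 against 0.03 for the forward strand, and it was the more increased strand in 31. Where the reverse-complement strand was dimmer by at least 2 log2 units in the mean of the arrays, it was higher after HDTAB in 15 of 15 sequences, with a median of 0.83 against -0.07 for the bright forward strand. A drift of dim probe sets with level is argued against, since the median of 0.32 stood at percentile 100 of matched lists of P. falciparum probe sets, whose central 95% ran from -0.06 to 0.11. Weaker strand specificity of the labelling may account for the rise. In the 4 sequences with a dimmer forward strand, the dim strand was higher after HDTAB in 4 with a median of 0.26, as this explanation asks, but the bright reverse-complement strand had a median of 0.42, and the dim strand was the more increased one in 2. With 4 sequences this cannot be decided, and a higher level of RNA matched by the reverse-complement probe sets after HDTAB remains open and untested. Whether such RNA would be antisense is not known, since the organism and the coding strand of these sequences are not given here.

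The controls added during processing were brighter on the HDTAB array. Less labelled cRNA on that array is argued against as the whole cause, because the poly-A controls are part of the same cRNA as the parasite transcripts and still had a median of 0.52, with every probe set above 0.2. A lower share of parasite mRNA in the spiked RNA, or a larger amount of spike, could give this. These cannot be told apart with 1 array per condition, and the further 0.34 by which the hybridisation controls exceeded the poly-A controls may reflect the amount of cRNA. A smaller amount of parasite mRNA under treatment remains open.

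The 5' probe set of parasite actin was higher by 1.40 while the 3' probe set was lower. An array-wide difference in RNA integrity or labelled length was not seen in GAPDH, whose 3' minus 5' difference changed by -0.043. For actin this difference was 5.88 untreated and 4.13 after HDTAB, a change of -1.75. With GAPDH as the only other parasite transcript, this cannot be decided. The poly-A controls were added to extracted RNA and do not report the integrity of parasite RNA. In 1 pair of probe sets per poly-A control this change ran from -0.40 for Lys to 0.00 for Phe. A second pair for Lys went the other way, its 3' set rising by 0.77 and its 5' set by 0.44. The measure was therefore unstable for Lys. The 5', middle and 3' actin probe sets all carry the suffix for shared probes. Another transcript that shares the 5' actin probes cannot be told apart from a change in actin itself. The middle probe set differed by 0.10, and probe sequences were not used here.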

How the results depend on the processing

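The counts of 52 higher and 69 lower targets stayed within 1.5 times under median centring, quantile normalization, loess, each background filter, each rule for probe sets of a target and dim values raised to background, with 42 to 55 higher and 57 to 72 lower. The deposited signals were already nearly aligned. Median centring, quantile normalization and loess shifted the median log2 difference by at most 0.022, so they could hardly change the counts and are a weak check. They moved with the threshold, to 219 and 306 at 1.5-fold and to 3 and 4 at 4-fold. Scaling to the hybridisation controls gave 6 higher and 1330 lower, and scaling to the poly-A controls gave 9 and 435, with GAPDH at -0.30 in the first, and histidine-rich protein III at -0.63 and -0.28. By construction these scalings set 1 class of controls to 0 and left the poly-A controls at -0.34 and the hybridisation controls at 0.34. The 4 named targets kept their direction under each setting in which they were measured, but their size moved with control scaling. Pf.6.59.0, at 2.02, was just past 4-fold and was under it with quantile normalization too, at 1.97. Under both control scalings Pf.11.257.0 and Pf.6.59.0 were under 4-fold higher, and with hybridisation and poly-A controls in turn Pf.3.169.0 was at -3.57 and -3.22 and Pf.7.207.0 at -3.05 and -2.70. Likewise the 5' actin probe set was at 0.54 and 0.88 and the 3' one at -1.22 and -0.87. Pf.11.257.0, Pf.6.59.0 and Pf.3.169.0 have no probe set without a suffix for shared or alternative transcripts. A background added before log2 was not run, since the table is already on a log scale, and no alternative was run for choline kinase, the gene lists or the stage lists, which have no value. Leaving out a replicate and a paired analysis were not possible with 1 array per group.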

Other observations

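Groups of P. falciparum probe sets formed from their IDs, after the values were seen, differed in places. The 146 measured probe sets with neither CDS nor UTR in the ID had a median log2 difference of 0.16, at percentile 100 of lists matched on level, and 8 of them were at least 2-fold higher after HDTAB while 0 were 2-fold lower. The 3679 CDS probe sets had a median of -0.02, with 46 at least 2-fold higher and 72 lower. The 60 probe sets with the s suffix, whose probes match several transcripts, had a median of 0.18 at percentile 99.98, and 10 of them were at least 2-fold higher and 1 lower, against 42 and 57 of 3404 without a suffix. The other suffixes for shared probes did not share this: of 231 probe sets with the a suffix (median -0.02) 1 was at least 2-fold higher and 10 lower, and of those with the x suffix (median -0.06, percentile 5.99) 1 (0.65%) was higher and 4 (2.6%) were lower. The first number of the ID, which runs over 14 values, separated little: medians ran from -0.08 for number 8 to 0.06 for number 1, and 2 of the 14, numbers 8 and 12 (median 0.02), lay outside the central 95% of matched lists.

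The share of P. falciparum probe sets that differed by at least 2-fold depended on level. Between log2 levels of 2.5 and 3, 2 were higher and 5 lower of 290 (2.4%). From 3 to 4 it was 8 and 5 of 360 (3.6%), from 4 to 5 it was 19 and 11 of 350 (8.6%), from 5 to 6 it was 7 and 10 of 423 (4.0%), from 6 to 8 it was 15 and 21 of 1205 (3.0%), from 8 to 10 it was 2 and 18 of 969 (2.1%), and above 10 it was 1 and 2 of 388 (0.77%).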
